A study of Mus musculus with 20 samples.

How the data were processed

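Total RNA of 2 mouse pancreatic tumour lines, AK192 and AK12282, was extracted with the RNeasy kit and sequenced on standard Illumina libraries, per the labels, from cells grown in RPMI1640 with 10% FBS. The authors deposited TPM (transcript abundance as a share of the library) for 53520 gene symbols in 20 libraries, and per the submitters' processing notes the reads were trimmed with fastp and quantified with Salmon 0.14.1 on mm10. The transcript annotation is not given in the sources used here, and neither enrichment of RNA classes nor scaling between libraries was stated for the deposited TPM. The symbols were looked up in GENCODE M21 for coordinates, where 52972 of 53520 (99.0%) were found, 107 of them at more than 1 gene. TPM do not give read counts, so depth and counting error were unknown, and count-based models were not used.

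The libraries formed 10 groups of 2, by line and treatment as in the sample titles. All 20 entered 1 limma fit (lmFit, contrasts.fit and eBayes with trend) of log2(TPM + 1) with 1 mean per group, which left 10 residual degrees of freedom, over the genes with at least 1 TPM in at least 2 libraries. Contrasts were DoxOFF, Tra, 2DG and Combo against DoxON, Combo against Tra and against 2DG, and Tra against DoxOFF, each as the mean of both lines, the non-additivity term (Combo minus Tra minus 2DG plus DoxON), the 4 DoxON contrasts within each line, and the 4 differences between the lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, two-sided. In a contrast over both lines, line and lane cancel. Gene lists were tested with camera, a competitive two-sided test, at the preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 22 lists within a contrast. The lists were fixed before the data were examined, as were the contrasts and the rule for named genes. They were ERK pathway output, glycolysis and glucose uptake, pentose phosphate and hexosamine, ER chaperones and ERAD, ATF4 and CHOP targets, cytosolic tRNA synthetases, N-glycosylation, pro-survival BCL2 family, pro-apoptotic BCL2 family and death receptor, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis and MYC targets, cholesterol synthesis, fatty acid synthesis, lysosome and autophagy, oxidative phosphorylation, interferon and antigen presentation, p53 targets, NRF2 targets, YAP and TEAD targets, epithelial and ductal, and mesenchymal genes. Lists of acinar, fibroblast, macrophage and leukocyte, and endothelial markers had 1 or 2 measured members and were given as levels only. Named genes were, in this order, 13 fixed genes (Kras, Dusp6, Spry4, Etv4, Ccnd1, Slc2a1, Hk2, Txnip, Arrdc4, Hspa5, Ddit3, Asns and Bcl2l11) in comparisons over both lines, then the 5 largest rises and 5 largest falls among called genes with the same sign in both lines and at least 5 TPM in the higher group of both lines, then up to 3 called members per called list with the smallest p. For non-additivity and the differences between lines they were the 5 highest and 5 lowest called values with at least 5 TPM in a group concerned. Symbols of predicted genes and clones (Gm, AC, BC, Rik) were left out of the ranking. Gm24245, Mir6236 and Gm42418 were named after their values were seen, as the 3 features with the highest TPM.

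Median-of-ratios size factors over genes above 0 in every library gave the rescaled values. The correlation of the DoxOFF and Tra changes was set beside a simulation of unchanged groups on the same controls, split controls and lines used crosswise. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, replicate number as a block, a fit of the compared groups only, robust eBayes, an estimated correlation for camera, and each library left out in turn. Alternatives added after seeing the data are named with the results. The test was checked on simulated data, with genes drawn independently and 200 changed for DoxOFF. It recovered 35.8% of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold changes with 12 false calls (7.55% of calls) on the deposited scale, and 73.1%, 89.6% and 93.9% with 9 false calls after rescaling. A list moved on purpose was called and 0 of 21 others were, which does not test lists of correlated genes. Work was done in R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9.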

Results

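RNA sequencing was available for 20 libraries from 2 mouse pancreatic ductal adenocarcinoma lines, AK192 and AK12282, whose labels give the genotype p48Cre, tetO-Kras, Rosa rtTA and p53, so that an oncogenic Kras transgene is switched on by doxycycline. Each line had 5 groups of 2 libraries. The groups were doxycycline on (DoxON), doxycycline off (DoxOFF), the MEK inhibitor trametinib at 25 nM (Tra), the glucose analogue 2-deoxyglucose at 1 mM (2DG) and both drugs (Combo), with 24 h of drug. The labels do not give the doxycycline state of the drug groups, and they do not say whether the duplicates came from separate cultures. The values were TPM for 53520 gene symbols, so read depth was unknown. The deposited columns summed to 943567 to 964051 TPM. A library held 19313 to 20886 genes above 0, except 12980 in AK192 2DG replicate 2. Over the genes tested, replicate libraries correlated at 0.979 to 0.983 across genes after rescaling, and at 0.938 for the AK192 2DG pair. Gm24245, Mir6236 and Gm42418 together took 7.64 to 44.8% of the TPM in AK192 and 4.25 to 18.8% in AK12282, and the DoxON libraries of AK192 differed most within a group, at 11.6 and 41.6%. Median-of-ratios size factors ran from 0.653 to 1.14 in AK192 and from 1.04 to 1.21 in AK12282. Markers of other pancreatic cell types were low. The group means stayed below 1 TPM in every group for 12 of 13 acinar, 9 of 11 fibroblast, 10 of 12 macrophage and leukocyte and 7 of 9 endothelial markers. Of the others, Cd14 (62.6 TPM), Egfl7 (14.8) and Col1a1 (11.7) had the highest group means.

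**Figure D1:**
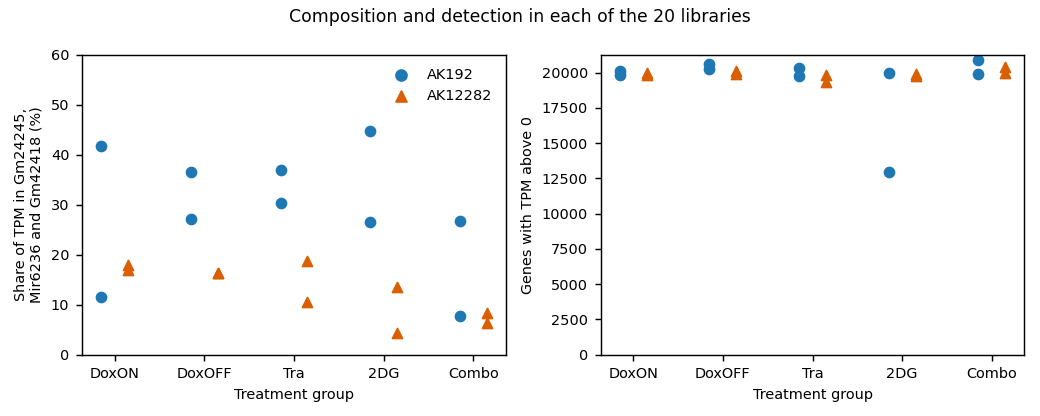
Each point is 1 library, by treatment group and line. The left axis gives the share of TPM in 3 noncoding features (%) and the right axis the number of genes above 0 TPM, lowest in AK192 2DG replicate 2 (12980).

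Fold changes below are log2 differences of TPM + 1, averaged over both lines with 4 libraries in each group unless a line is named, and the value after ± is the standard error. They understate changes of genes near or below 1 TPM. The limma p-values measure only the spread between these duplicates. Each gene named as called over both lines moved that way in all 4 treated libraries, relative to its line's mean deposited log2 reference value. Genes passing only after rescaling did not all do so. Of 53520 genes, 13645 reached 1 TPM in at least 2 libraries and were tested. Because TPM are shares of a library, counts are given as deposited and after median-of-ratios rescaling. For lists, the count marked as rescaled is that of members passing over all genes after rescaling. The calls held 0 genes with opposite directions as deposited and rescaled. With an estimated correlation between genes, camera called 0 of 22 lists at an adjusted p under 0.05 on the deposited values in any of the 8 comparisons over both lines, so each list call below rests on the preset correlation of 0.01 unless stated.

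DoxOFF against DoxON asked which transcripts moved when the Kras transgene was no longer induced. Kras itself, which the GRCm38 annotation placed on chromosome 6 at 145216699 to 145250239, fell by 0.85 ± 0.16 (adjusted p = 0.011), from 103 ± 32.7 to 52.3 ± 6.33 TPM (SD, n = 2) in AK192 and from 114 ± 2.64 to 66.5 ± 5.91 TPM in AK12282. The symbol-level value cannot separate the transgene from the endogenous gene. Feedback regulators and transcription factors that follow ERK signalling fell with it: Dusp6 (-1.06 ± 0.15), Spry4 (-1.04 ± 0.14), Etv4 (-1.40 ± 0.33), Etv5 (-1.53 ± 0.20) and Dusp5 (-1.17 ± 0.15), with limma adjusted p of at most 0.0379. The glucose transporter gene Slc2a1 (-0.61 ± 0.14) and the hexokinase gene Hk2 (-0.60 ± 0.14) also fell (adjusted p of at most 0.035), and Txnip, an arrestin-family gene that restrains glucose uptake, rose (1.50 ± 0.15, adjusted p = 0.000205). The largest rise was that of Bmf, a BH3-only pro-apoptotic gene, at 1.68 ± 0.14. Rbp2 (1.48 ± 0.12), Tmigd1 (1.35 ± 0.19) and Tgfb2 (1.33 ± 0.11) followed (adjusted p of at most 0.00156). Among the largest falls were the chromatin gene Hmga2 (-1.27 ± 0.17) and the uridine phosphorylase gene Upp1 (-1.27 ± 0.14), with adjusted p of at most 0.000939. Mir7651 was also called down (adjusted p = 0.035) and was listed at 0 in all DoxOFF libraries, against 10.0, 3.64, 12.2 and 0 TPM in DoxON. Ccnd1 (-0.42 ± 0.17), Arrdc4 (0.07 ± 0.13), Hspa5 (-0.04 ± 0.13), Ddit3 (-0.15 ± 0.11), Asns (-0.52 ± 0.13) and Bcl2l11 (0.24 ± 0.18) did not pass, with adjusted p of 0.0566 to 1. Of these, Ccnd1, Hspa5 and Asns passed after rescaling (adjusted p of at most 0.0279).

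**Figure D2:**
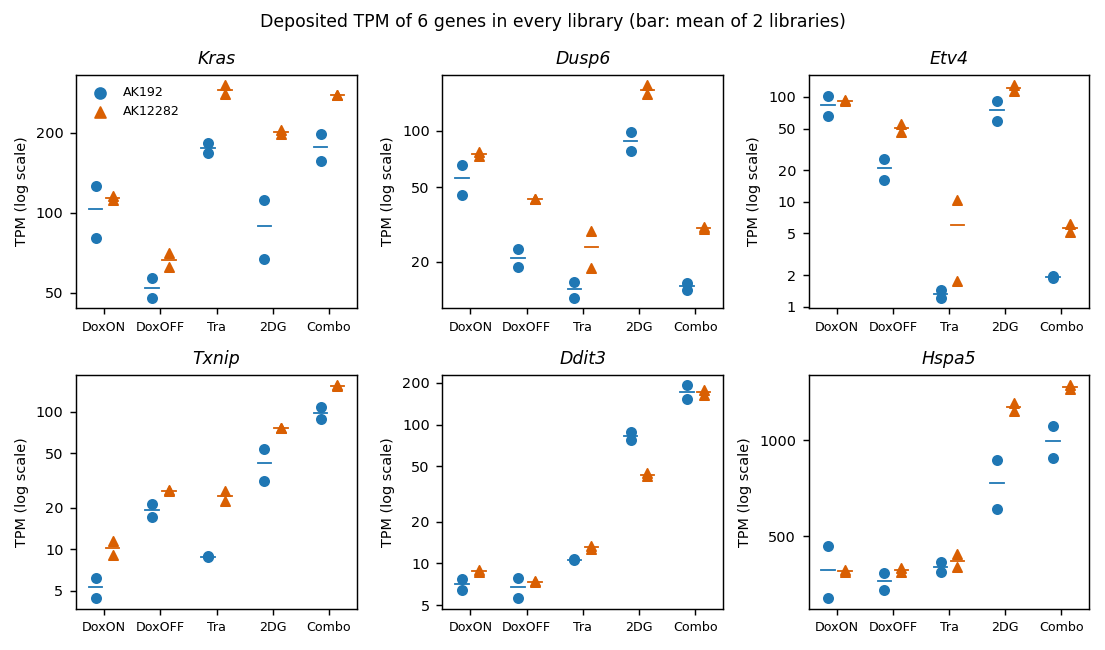
Deposited TPM on a log axis for Kras, Dusp6, Etv4, Txnip, Ddit3 and Hspa5 in each library, by treatment group and line, with a bar at the mean of the 2 libraries. Mean Etv4 in AK192 was 84.4 TPM in DoxON and 1.32 TPM in Tra.

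In ERK pathway output, a list fixed in advance like the others, 8 of 24 measured members fell, 1 rose and 15 did not pass (13 fell and 1 rose adjusted over the list alone, 17 and 1 rescaled), with camera adjusted p = 1.39e-16 (adjusted p = 0.697 with estimated correlation). Glycolysis and glucose uptake was called down, where 2 of 21 fell and 19 did not pass (3 fell and 1 rose adjusted over the list alone, 13 and 2 rescaled), with camera adjusted p = 0.000272 (0.797 with estimated correlation). Rescaled values gave adjusted p = 0.0468 with an estimated correlation. The ATF4 and CHOP targets of the amino acid and stress response were called down, with camera adjusted p = 1.33e-11 (0.697 with estimated correlation). Of these, 4 of 30 fell, 2 rose and 24 did not pass (14 fell and 2 rose adjusted over the list alone, 19 and 2 rescaled), with Trib3 at -1.05 ± 0.14, Cth at -0.70 ± 0.13 and Chac1 at -0.73 ± 0.14. For the cytosolic tRNA synthetases, 0 of 17 passed limma's test over all genes (3 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone (15 fell over all genes after rescaling), with a median of -0.15 and camera adjusted p = 8.9e-06 (0.697 with estimated correlation). After rescaling, both lists were called down with an estimated correlation too, at adjusted p = 0.0167. Ribosome biogenesis and MYC targets had a median of -0.22, where 0 of 24 passed limma's test over all genes (4 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone (19 fell over all genes after rescaling), with camera adjusted p = 7.9e-09 (0.697 with estimated correlation). Of the pro-apoptotic genes, 2 of 11 rose and 9 did not pass (2 rose adjusted over the list alone, 3 rescaled), Bmf and Pmaip1 (0.83 ± 0.12), with camera adjusted p = 0.00389 (0.697 with estimated correlation). Of NRF2 targets of the oxidative stress response, 4 of 15 rose and 11 did not pass (5 rose adjusted over the list alone, 8 rescaled). Gsta4 was at 0.92 ± 0.13, with camera adjusted p = 4.05e-06 (0.697 with estimated correlation). With both rescaling and an estimated correlation it was called too, at adjusted p = 0.0167. For interferon and antigen presentation, 1 of 18 rose and 17 did not pass (2 rose and 1 fell adjusted over the list alone, 6 and 1 rescaled), namely Cxcl10 (0.84 ± 0.12), with camera adjusted p = 0.00161 (0.697 with estimated correlation). Cholesterol synthesis had a median of 0.22, where 0 of 23 passed limma's test over all genes (7 at an unadjusted p under 0.05), and 1 rose adjusted over the list alone (9 rose and 1 fell over all genes after rescaling), with camera adjusted p = 0.000272 (0.863 with estimated correlation). Over all genes, 272 rose and 89 fell with DoxOFF, and after rescaling 1126 rose and 1353 fell. With 1 library left out the total ranged from 148 to 600.

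Tra against DoxON asked what MEK inhibition changed. The largest fall was that of Etv4, a transcription factor gene downstream of ERK, by 4.61 ± 0.33, from 84.4 ± 25.6 to 1.32 ± 0.152 TPM (SD, n = 2) in AK192 and from 92.0 ± 1.52 to 6.07 ± 6.12 TPM in AK12282, where the 2 Tra libraries differed at 10.4 and 1.74 TPM. Dusp6 (-1.76 ± 0.15), Spry4 (-1.56 ± 0.14), Etv5 (-3.11 ± 0.20) and the cyclin D1 gene Ccnd1 (-1.15 ± 0.17) fell as well, with limma adjusted p of at most 0.000183. Kras rose by 1.07 ± 0.16 (adjusted p = 0.000226). Slc2a1 (-0.61 ± 0.14), Hk2 (-0.59 ± 0.14) and Asns (-0.54 ± 0.13) fell, while Txnip (0.92 ± 0.15), Ddit3 (0.53 ± 0.11) and Bcl2l11, the gene of the BH3-only protein BIM (0.69 ± 0.18), rose, with adjusted p of at most 0.0103. Arrdc4 (-0.16 ± 0.13) and Hspa5 (0.08 ± 0.13) did not pass, with adjusted p of 0.369 to 0.677. The largest rises were in the matrix gene Spon2 (3.86 ± 0.15), Bmf (3.55 ± 0.14), the autophagy gene Trp53inp2 (3.38 ± 0.15), S100g (3.28 ± 0.25) and AW112010 (3.23 ± 0.15), and the largest falls besides Etv4 and Etv5 were in the proliferin genes Prl2c2 (-3.38 ± 0.16) and Prl2c3 (-3.29 ± 0.13) and the mannose receptor gene Mrc1 (-3.03 ± 0.21), with adjusted p of at most 5.22e-07. Prl2c2 and Prl2c3 are close paralogs that share reads.

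Of the ERK output list, 18 of 24 measured members fell, 1 rose and 5 did not pass (19 fell and 1 rose adjusted over the list alone, 19 and 1 rescaled). Ereg was at -1.92 ± 0.13, with camera adjusted p = 1.09e-12 (0.59 with estimated correlation). Of ribosome biogenesis and MYC targets, 23 of 24 fell and 1 did not pass (24 fell adjusted over the list alone, 24 rescaled). Odc1 was at -1.27 ± 0.15, with camera adjusted p = 1.3e-16 (0.59 with estimated correlation). In G1/S and DNA replication, 27 of 30 fell and 3 did not pass (28 fell adjusted over the list alone, 29 rescaled). Tk1 was at -1.37 ± 0.17, with camera adjusted p = 3.38e-14 (0.59 with estimated correlation). Of the G2/M and mitosis genes, 16 of 25 fell and 9 did not pass (20 fell adjusted over the list alone, 23 rescaled). Kif23 was at -0.90 ± 0.15, with camera adjusted p = 4.78e-08 (0.665 with estimated correlation). Glycolysis and glucose uptake was called down, where 9 of 21 fell, 3 rose and 9 did not pass (9 fell and 3 rose adjusted over the list alone, 16 and 3 rescaled). Slc16a1 was at -0.85 ± 0.16, with camera adjusted p = 0.00481 (0.811 with estimated correlation). ATF4 and CHOP targets went both ways, where 12 of 30 fell, 6 rose and 12 did not pass (12 fell and 6 rose adjusted over the list alone, 15 and 7 rescaled), Cth (-1.53 ± 0.13) and Slc7a11 (-1.38 ± 0.18) down and Ddit3 up, with camera adjusted p = 0.0193 (0.944 with estimated correlation). Among tRNA synthetases, 2 of 17 fell and 15 did not pass (2 fell adjusted over the list alone, 16 rescaled), Vars (-0.62 ± 0.15) and Cars (-0.51 ± 0.13), with camera adjusted p = 0.00075 (0.811 with estimated correlation). Of lysosome and autophagy genes, 23 of 31 rose and 8 did not pass (25 rose adjusted over the list alone, 27 rose and 1 fell rescaled). Map1lc3a was at 1.66 ± 0.12, with camera adjusted p = 2.51e-09 (0.665 with estimated correlation). Of interferon and antigen presentation genes, 16 of 18 rose and 2 did not pass (17 rose adjusted over the list alone, 17 rescaled). Ddx58 was at 1.30 ± 0.14, with camera adjusted p = 2.52e-07 (0.59 with estimated correlation). After rescaling this was adjusted p = 0.049 with an estimated correlation. Of pro-apoptotic genes, 7 of 11 rose and 4 did not pass (8 rose adjusted over the list alone, 10 rose and 1 fell rescaled). Pmaip1 was at 2.13 ± 0.12, with camera adjusted p = 0.000242 (0.601 with estimated correlation). Of YAP and TEAD targets, 13 of 21 rose, 2 fell and 6 did not pass (13 rose and 2 fell adjusted over the list alone, 14 and 3 rescaled). Tgfb2 was at 2.66 ± 0.11, with camera adjusted p = 9.52e-05 (0.721 with estimated correlation). For the mesenchymal list, 4 of 11 rose and 7 did not pass (5 rose and 1 fell adjusted over the list alone, 6 and 2 rescaled). Serpine1 was at 1.60 ± 0.13, with camera adjusted p = 0.0166 (0.811 with estimated correlation). The fibroblast marker Col1a1 had 11.7 TPM in AK12282 Tra against 1.28 in DoxON. Over all genes, 2907 rose and 1508 fell with Tra, and after rescaling 4050 rose and 3617 fell.

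**Figure D3:**
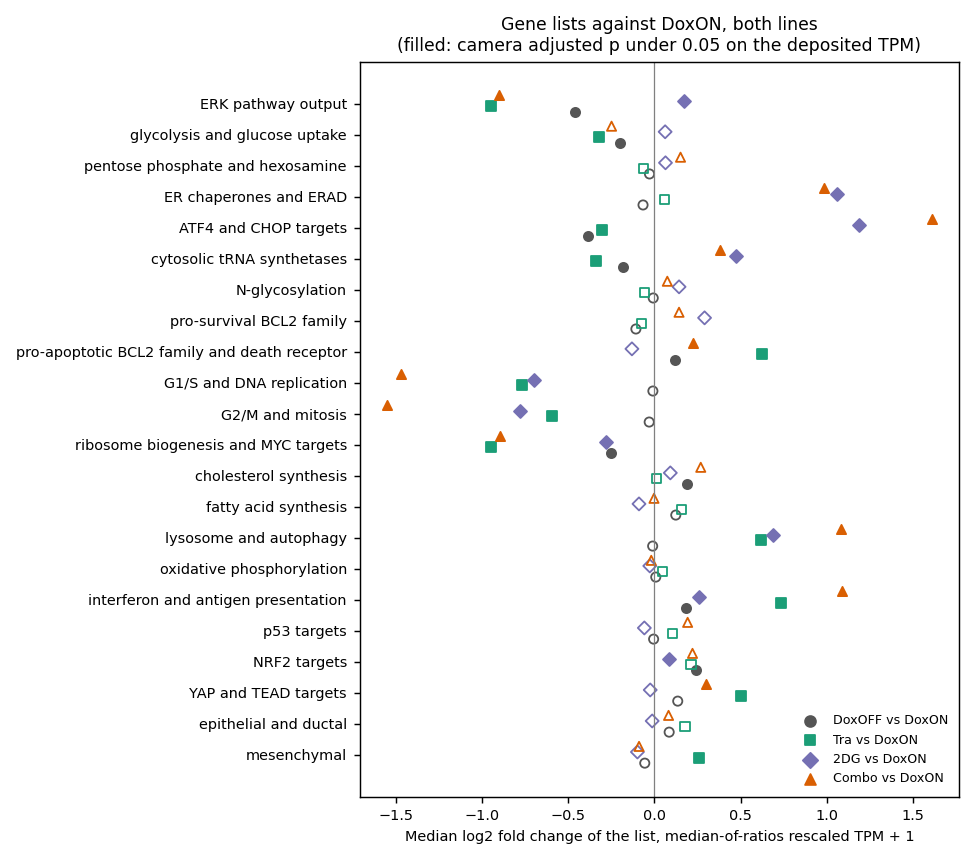
Median log2 fold change against DoxON of each of the 22 tested gene lists, after median-of-ratios rescaling, for DoxOFF, Tra, 2DG and Combo over both lines. Filled symbols mark lists with a camera adjusted p under 0.05 on the deposited TPM with the preset correlation. The ATF4 and CHOP target list lay at 1.61 in Combo and 1.19 in 2DG.

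The DoxOFF and Tra responses were compared because both lower ERK output. Both comparisons called 250 genes up, 80 down and 2 in opposite directions (rescaled, 1003, 1099 and 125). Across 13645 genes, which are not independent replicates, the fold changes correlated at r = 0.597 and rho = 0.627. Both used the same DoxON libraries, and a simulation of unchanged groups with these shared controls gave r = 0.500 and a covariance of 0.0289, against a covariance of 0.0927 in the data. With DoxON replicates split between the comparisons, both called 92 up and 62 down in one split and 232 and 22 in the other, against 23.7 and 4.56, and 35.1 and 3.45, if the calls were independent. After rescaling these were 605 and 609, and 505 and 523, against 166 and 168, and 145 and 151. In these splits, r was 0.377 and 0.352 with covariances of 0.0704 and 0.0646, and with DoxOFF from one line and Tra from the other, r was 0.316 (DoxOFF in AK192) and 0.201 (DoxOFF in AK12282).

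Set against DoxOFF directly, Tra had higher Kras (1.92 ± 0.16) and lower Etv4 (-3.21 ± 0.33), Dusp6 (-0.70 ± 0.15), Spry4 (-0.52 ± 0.14) and Ccnd1 (-0.74 ± 0.17), with limma adjusted p of at most 0.022. Ddit3 was higher (0.68 ± 0.11) and Txnip lower (-0.58 ± 0.15), with adjusted p of at most 0.0184. The change was -0.20 in AK192 and -0.83 in AK12282 for Spry4 and -1.03 in AK192 and -0.12 in AK12282 for Txnip. Slc2a1 (0.00 ± 0.14), Hk2 (0.01 ± 0.14), Arrdc4 (-0.24 ± 0.13), Hspa5 (0.12 ± 0.13), Asns (-0.02 ± 0.13) and Bcl2l11 (0.45 ± 0.18) did not pass (adjusted p of 0.101 to 1). Of these, Hspa5 and Bcl2l11 passed after rescaling (adjusted p of at most 0.0119). The largest rises were in Klhl30 (2.61 ± 0.14), Trp53inp2 (2.45 ± 0.15), Spon2 (2.41 ± 0.15), the small heat shock gene Cryab (2.39 ± 0.15) and AW112010 (2.26 ± 0.15), and the largest falls those of Prl2c2 (-3.52 ± 0.16) and Prl2c3 (-3.40 ± 0.13), with adjusted p of at most 7.05e-07. Mir7679 and Mir207 were also called down (adjusted p of 0.0278 to 0.0397) and were listed at 0 in all Tra libraries. In DoxOFF, Mir7679 had 30.3, 0, 9.82 and 22.8 TPM and Mir207 had 13.6, 0, 17.2 and 17.3 TPM.

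Of the G1/S genes, 27 of 30 measured members fell and 3 did not pass (29 fell adjusted over the list alone, 29 rescaled). Tk1 was at -1.18 ± 0.17, with camera adjusted p = 8.06e-19 (0.524 with estimated correlation). For G2/M and mitosis, 15 of 25 fell and 10 did not pass (21 fell adjusted over the list alone, 25 rescaled). Kif23 was at -0.89 ± 0.15, with camera adjusted p = 5.46e-11 (0.524 with estimated correlation). Of ribosome biogenesis genes, 20 of 24 fell and 4 did not pass (22 fell adjusted over the list alone, 23 rescaled). Ncl was at -0.97 ± 0.16, with camera adjusted p = 1.9e-15 (0.524 with estimated correlation). In the ERK output list, 12 of 24 fell and 12 did not pass (14 fell adjusted over the list alone, 16 fell and 2 rose rescaled). Egr1 was at -2.51 ± 0.16, with camera adjusted p = 4.88e-08 (0.533 with estimated correlation). Cholesterol synthesis was called lower, with a median of 0.08 in AK192 and -0.32 in AK12282 (rescaled, 0.10 and -0.42), where 1 of 23 fell and 22 did not pass (1 fell adjusted over the list alone, 12 fell and 2 rose rescaled), namely Pcsk9 (-0.73 ± 0.14), with camera adjusted p = 0.0346 (0.87 with estimated correlation). Of lysosome and autophagy genes, 25 of 31 rose and 6 did not pass (27 rose adjusted over the list alone, 29 rescaled). Atp6v0d1 was at 1.35 ± 0.12, with camera adjusted p = 8.77e-14 (0.524 with estimated correlation). Of interferon and antigen presentation genes, 16 of 18 rose and 2 did not pass (16 rose adjusted over the list alone, 16 rescaled). B2m was at 0.88 ± 0.13, with camera adjusted p = 1.04e-06 (0.524 with estimated correlation). Among pro-apoptotic genes, 5 of 11 rose and 6 did not pass (5 rose adjusted over the list alone, 8 rose and 1 fell rescaled). Bmf was at 1.87 ± 0.14, with camera adjusted p = 0.00028 (0.524 with estimated correlation). Of YAP and TEAD targets, 11 of 21 rose, 1 fell and 9 did not pass (12 rose and 1 fell adjusted over the list alone, 15 and 2 rescaled). Cyr61 was at 1.52 ± 0.12, with camera adjusted p = 1.21e-05 (0.57 with estimated correlation). In the mesenchymal list, 5 of 11 rose and 6 did not pass (7 rose adjusted over the list alone, 8 rose and 1 fell rescaled). Fn1 was at 1.37 ± 0.15, with camera adjusted p = 0.000546 (0.57 with estimated correlation). Over all genes, 1886 rose and 911 fell in Tra relative to DoxOFF, and after rescaling 3543 rose and 2984 fell. With 1 library left out the total ranged from 1582 to 3877.

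2DG against DoxON asked what 2-deoxyglucose changed. Glucose use was not measured. The 2DG groups had higher transcripts of the integrated stress response, the programme run by ATF4 and CHOP: Ddit3, the gene of CHOP, rose by 2.79 ± 0.11, from 7.06 ± 0.916 to 83.5 ± 7.85 TPM (SD, n = 2) in AK192 and from 8.82 ± 0.146 to 43.6 ± 1.61 TPM in AK12282. The mitochondrial folate enzyme gene Aldh1l2 (3.71 ± 0.15), the transcription factor gene Atf5 (3.28 ± 0.13), Cth (3.01 ± 0.13) and Trib3 (2.91 ± 0.14) made up the other largest rises, and the asparagine synthetase gene Asns rose by 1.20 ± 0.13, with limma adjusted p of at most 5.33e-05. Hspa5, the gene of the ER chaperone BiP, rose by 1.31 ± 0.13. Txnip, which responds to glucose phosphates, rose by 2.77 ± 0.15 (adjusted p of at most 2.9e-05). Its relative Arrdc4 was called over both lines (0.67 ± 0.13, adjusted p = 0.00307), but its change was 1.31 in AK192 and 0.03 in AK12282, where it was near 0 TPM in DoxON (0.0447) and 2DG (0.0677). The ERK feedback genes Dusp6 (0.90 ± 0.15) and Spry4 (0.70 ± 0.14) rose (adjusted p of at most 0.00514), and Kras (0.30 ± 0.16), Etv4 (0.12 ± 0.33), Ccnd1 (0.00 ± 0.17), Slc2a1 (0.35 ± 0.14), Hk2 (0.27 ± 0.14) and Bcl2l11 (-0.43 ± 0.18) did not pass, with adjusted p of 0.0905 to 0.999. Of these, Kras, Slc2a1, Hk2 and Bcl2l11 passed after rescaling (adjusted p of at most 0.0219). Sprr1a, a gene of the cornified envelope, fell by 2.35 ± 0.14 (adjusted p = 2.24e-07). Mir3109, Mir1945, Mir6904 and the histone gene Hist1h2ai, whose paralogs share sequence, were called down (adjusted p of 0.00386 to 0.0266), and the 3 microRNA genes were listed at 0 in all 2DG libraries. Those libraries included AK192 2DG replicate 2, which had only 12980 genes above 0. Their DoxON values were 7.52, 32.6, 7.58 and 23.0 TPM for Mir3109, 0, 23.5, 58.0 and 19.3 for Mir1945 and 9.84, 2.98, 7.63 and 10.1 for Mir6904.

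Of the ATF4 and CHOP targets, 26 of 30 measured members rose and 4 did not pass (28 rose adjusted over the list alone, 30 rescaled), with camera adjusted p = 2.05e-34 (0.262 with estimated correlation). Of ER chaperones and ERAD genes, 24 of 27 rose and 3 did not pass (25 rose adjusted over the list alone, 26 rescaled). Herpud1 was at 1.53 ± 0.15, with camera adjusted p = 1.04e-25 (0.299 with estimated correlation). After rescaling, both lists were called up with an estimated correlation too, at adjusted p = 0.00124 and 0.000545. Among tRNA synthetases, 6 of 17 rose and 11 did not pass (12 rose adjusted over the list alone, 13 rose and 3 fell rescaled). Sars was at 1.10 ± 0.13, with camera adjusted p = 3.66e-05 (0.809 with estimated correlation). Of lysosome and autophagy genes, 21 of 31 rose, 1 fell and 9 did not pass (25 rose and 1 fell adjusted over the list alone, 26 and 2 rescaled). Sqstm1 was at 1.70 ± 0.12, with camera adjusted p = 3.5e-15 (0.5 with estimated correlation). The ERK output list was called up, with a median of -0.15 in AK192 and 0.41 in AK12282, where 5 of 24 rose and 19 did not pass (5 rose adjusted over the list alone, 13 rose and 2 fell rescaled). Dusp4 was at 1.09 ± 0.15, with camera adjusted p = 0.00952 (0.933 with estimated correlation). For interferon and antigen presentation, 5 of 18 rose, 2 fell and 11 did not pass (5 rose and 3 fell adjusted over the list alone, 9 and 3 rescaled). Oasl1 was at 0.69 ± 0.12, with camera adjusted p = 0.0161 (0.809 with estimated correlation). The NRF2 targets were called up although their median was -0.00443 against a mean of 0.21, and the median was 0.09 after rescaling (as deposited, -0.16 in AK192 and 0.27 in AK12282), where 5 of 15 rose and 10 did not pass (7 rose and 1 fell adjusted over the list alone, 7 and 4 rescaled). Gstm1 was at 1.12 ± 0.11, with camera adjusted p = 0.0196 (0.933 with estimated correlation). Of the G1/S genes, 28 of 30 fell and 2 did not pass (28 fell adjusted over the list alone, 28 rescaled). Rrm2 was at -1.28 ± 0.16, with camera adjusted p = 4.87e-14 (0.5 with estimated correlation). For G2/M and mitosis, 24 of 25 fell and 1 did not pass (25 fell adjusted over the list alone, 25 rescaled). Bub1b was at -0.95 ± 0.14, with camera adjusted p = 1.28e-14 (0.5 with estimated correlation). In ribosome biogenesis, 11 of 24 fell and 13 did not pass (13 fell and 1 rose adjusted over the list alone, 18 and 1 rescaled). Ddx21 was at -0.80 ± 0.15, with camera adjusted p = 9.09e-05 (0.809 with estimated correlation). Over all genes, 1130 rose and 1493 fell with 2DG, and after rescaling 3172 rose and 3380 fell. With 1 library left out the total ranged from 1293 to 5441.

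Combo against DoxON asked what trametinib and 2-deoxyglucose changed together. Rescaling lowered the changes by a median of 0.17, so values are those after rescaling, with limma adjusted p from the deposited values. The combination had low ERK output and high stress response transcripts at once: Etv4 fell by 4.48 ± 0.29, and Dusp6 (-1.73 ± 0.09), Spry4 (-1.25 ± 0.10) and Ccnd1 (-0.91 ± 0.08) fell, while Ddit3 rose by 4.10 ± 0.08, from 7.06 ± 0.916 to 172 ± 27.2 TPM as deposited (SD, n = 2) in AK192 and from 8.82 ± 0.146 to 171 ± 8.91 TPM in AK12282. Hspa5 (1.45 ± 0.02), Asns (1.25 ± 0.05), Txnip (3.71 ± 0.09) and Kras (0.85 ± 0.06) rose and Slc2a1 fell (-0.57 ± 0.05), all with adjusted p of at most 0.0323. Arrdc4 was called (0.70 ± 0.10, adjusted p = 0.00034), with a deposited change of 1.39 in AK192 and 0.09 in AK12282. Hk2 (0.02 ± 0.05) and Bcl2l11 (0.23 ± 0.12) did not pass (adjusted p of 0.0931 to 0.273). The largest rises were in the corneodesmosin gene Cdsn (5.44 ± 0.13), Aldh1l2 (4.26 ± 0.06), Ddit3, the invariant chain gene Cd74 (3.86 ± 0.15) and the glycogen-binding gene Stbd1 (3.83 ± 0.07). Besides Etv4, the largest falls were those of Mrc1 (-3.96 ± 0.14) and the cardiac troponin gene Tnnt2 (-3.23 ± 0.12), with adjusted p of at most 1.52e-08. Mir8105 and Mir6904 were also called down (adjusted p of 0.00132 to 0.00712) and were listed at 0 in all Combo libraries. In DoxON, Mir8105 had 7.18, 4.41, 7.19 and 14.6 TPM.

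In G1/S and DNA replication, 30 of 30 measured members fell (30 fell adjusted over the list alone, 30 rescaled). Rrm2 was at -2.17 ± 0.07, with camera adjusted p = 4.11e-23 (0.342 with estimated correlation). In G2/M and mitosis, 25 of 25 fell (25 fell adjusted over the list alone, 25 rescaled). Birc5 was at -1.82 ± 0.08, with camera adjusted p = 2.99e-21 (0.342 with estimated correlation). Of the ERK output genes, 17 of 24 fell, 2 rose and 5 did not pass (18 fell and 2 rose adjusted over the list alone, 20 and 2 rescaled). Dusp5 was at -2.46 ± 0.08, with camera adjusted p = 2.51e-10 (0.394 with estimated correlation). Of ribosome biogenesis genes, 20 of 24 fell and 4 did not pass (21 fell adjusted over the list alone, 23 rescaled). Dkc1 was at -1.23 ± 0.08, with camera adjusted p = 8.2e-12 (0.394 with estimated correlation). Of ATF4 and CHOP targets, 28 of 30 rose and 2 did not pass (29 rose adjusted over the list alone, 28 rescaled). Atf5 was at 3.78 ± 0.04, with camera adjusted p = 4.79e-16 (0.372 with estimated correlation). Of ER chaperones, 25 of 27 rose and 2 did not pass (26 rose adjusted over the list alone, 26 rescaled). Herpud1 was at 2.21 ± 0.04, with camera adjusted p = 1.59e-10 (0.394 with estimated correlation). For lysosome and autophagy, 29 of 31 rose and 2 did not pass (29 rose adjusted over the list alone, 29 rose and 1 fell rescaled). Sqstm1 was at 2.50 ± 0.06, with camera adjusted p = 9.07e-13 (0.394 with estimated correlation). For interferon and antigen presentation, 16 of 18 rose and 2 did not pass (16 rose adjusted over the list alone, 15 rescaled). Irf9 was at 1.99 ± 0.07, with camera adjusted p = 1.7e-07 (0.342 with estimated correlation). After rescaling, the ATF4, ER and interferon lists were called up with an estimated correlation too, at adjusted p = 0.00763, 0.00556 and 0.0135. Among tRNA synthetases, 13 of 17 rose and 4 did not pass (13 rose and 1 fell adjusted over the list alone, 12 and 4 rescaled). Sars was at 1.43 ± 0.03, with camera adjusted p = 0.0153 (0.904 with estimated correlation). Pro-apoptotic genes were called up, where 6 of 11 rose and 5 did not pass (6 rose adjusted over the list alone, 6 rose and 2 fell rescaled). Pmaip1 was at 1.91 ± 0.08, with camera adjusted p = 0.0153 (0.713 with estimated correlation). YAP and TEAD targets were called up, where 13 of 21 rose, 3 fell and 5 did not pass (14 rose and 3 fell adjusted over the list alone, 13 and 6 rescaled). Gadd45a was at 3.50 ± 0.10, with camera adjusted p = 0.0333 (0.904 with estimated correlation). Rescaling ended the calls of these last 2 lists, at camera adjusted p = 0.0735 and 0.101. Over all genes, 4382 rose and 1832 fell with Combo, and after rescaling 4459 rose and 4060 fell.

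**Figure D4:**
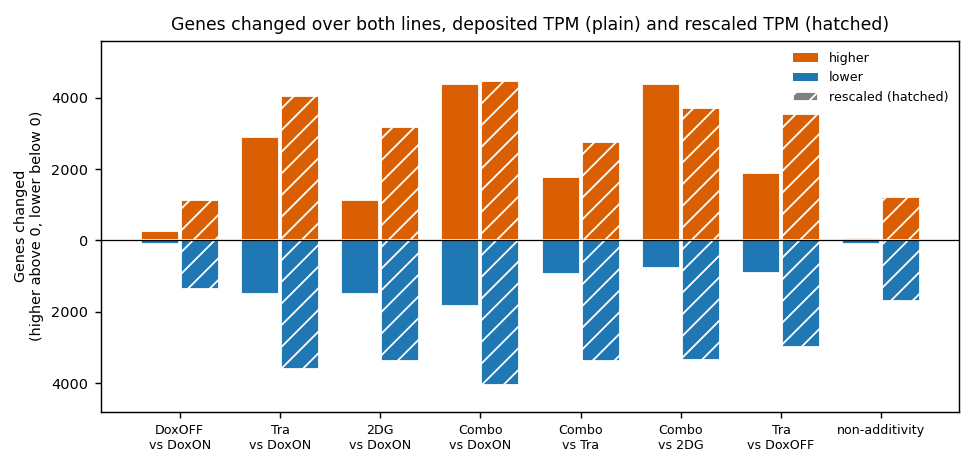
Number of genes with a limma adjusted p under 0.05 in each comparison over both lines, higher above 0 and lower below 0, on the deposited TPM (plain bars) and after median-of-ratios rescaling (hatched bars). For Combo against DoxON, 4382 were higher as deposited.

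Combo against Tra asked what 2-deoxyglucose added to MEK inhibition. Rescaling lowered the changes by a median of 0.11, and values are again those after rescaling. The added drug raised Ddit3 (3.64 ± 0.08), Asns (1.87 ± 0.05), Hspa5 (1.44 ± 0.02), Txnip (2.86 ± 0.09), Arrdc4 (0.86 ± 0.10) and Hk2 (0.68 ± 0.05), with limma adjusted p of at most 0.00129. Of these, Arrdc4 had a deposited change of 1.65 in AK192 and 0.15 in AK12282, and Hk2 of 1.39 in AK192 and 0.19 in AK12282. Kras (-0.14 ± 0.06), Dusp6 (0.10 ± 0.09), Spry4 (0.34 ± 0.10), Etv4 (0.22 ± 0.29), Ccnd1 (0.32 ± 0.08), Slc2a1 (0.11 ± 0.05) and Bcl2l11 (-0.40 ± 0.12) did not pass (adjusted p of 0.0637 to 0.938). Of these, Spry4, Ccnd1 and Bcl2l11 passed after rescaling (adjusted p of at most 0.0147). Aldh1l2 (4.82 ± 0.06), Cdsn (4.59 ± 0.13), Trib3 (4.34 ± 0.07) and Atf5 (4.07 ± 0.04) rose most. Sprr1a (-3.43 ± 0.09), the chemokine gene Ccl9 (-2.67 ± 0.16), Serpine1, the gene of plasminogen activator inhibitor (-2.55 ± 0.06), Sprr2a2 (-2.00 ± 0.26) and the complement gene C3 (-2.00 ± 0.10) fell most, with adjusted p of at most 2e-05. Mir677 was called up (adjusted p = 0.029) and was listed at 0 in all Tra libraries, against 22.2, 12.7, 35.9 and 43.0 TPM in Combo.

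Of ATF4 and CHOP targets, 29 of 30 measured members rose and 1 did not pass (29 rose adjusted over the list alone, 29 rose and 1 fell rescaled, median 1.68), with camera adjusted p = 5.69e-34 (0.272 with estimated correlation). Of ER chaperones, 24 of 27 rose and 3 did not pass (24 rose adjusted over the list alone, 25 rescaled). Herpud1 was at 1.88 ± 0.04, with camera adjusted p = 2.38e-19 (0.371 with estimated correlation). Of tRNA synthetases, 13 of 17 rose and 4 did not pass (14 rose adjusted over the list alone, 13 rose and 1 fell rescaled). Sars was at 1.53 ± 0.03, with camera adjusted p = 4.64e-10 (0.468 with estimated correlation). After rescaling, these lists were called up with an estimated correlation too, at adjusted p = 0.000729, 0.000677 and 0.0291. N-glycosylation, the sugar transfer pathway of the ER, was called up, where 7 of 30 rose and 23 did not pass (9 rose adjusted over the list alone, 12 rose and 3 fell rescaled). Pmm1 was at 0.70 ± 0.10, with camera adjusted p = 0.0269 (0.958 with estimated correlation). Cholesterol synthesis was called up, where 6 of 23 rose and 17 did not pass (7 rose adjusted over the list alone, 13 rose and 2 fell rescaled). Mvd was at 0.75 ± 0.08, with camera adjusted p = 0.00246 (0.958 with estimated correlation). In lysosome and autophagy, 22 of 31 rose, 1 fell and 8 did not pass (22 rose and 1 fell adjusted over the list alone, 22 and 4 rescaled). Sqstm1 was at 1.62 ± 0.06, with camera adjusted p = 1.03e-09 (0.593 with estimated correlation). In interferon and antigen presentation, 11 of 18 rose, 1 fell and 6 did not pass (13 rose and 1 fell adjusted over the list alone, 11 and 3 rescaled). Irf9 was at 1.31 ± 0.07, with camera adjusted p = 0.000614 (0.501 with estimated correlation). Of G1/S genes, 20 of 30 fell and 10 did not pass (26 fell adjusted over the list alone, 29 rescaled). Rrm2 was at -1.48 ± 0.07, with camera adjusted p = 2.7e-15 (0.468 with estimated correlation). Of G2/M genes, 24 of 25 fell and 1 did not pass (25 fell adjusted over the list alone, 25 rescaled). Ccnb2 was at -1.25 ± 0.05, with camera adjusted p = 8.05e-21 (0.371 with estimated correlation). Of the mesenchymal list, 5 of 11 fell, 1 rose and 5 did not pass (6 fell and 1 rose adjusted over the list alone, 8 and 1 rescaled). Snai1 was at -1.52 ± 0.19, with camera adjusted p = 0.000635 (0.644 with estimated correlation). Over all genes, 1768 rose and 930 fell in Combo relative to Tra, and after rescaling 2763 rose and 3378 fell. Across genes it correlated at r = 0.549 with 2DG against DoxON, which shares no libraries with it. Both called 762 genes up and 497 down, against 146 and 102 if independent (rescaled, 1871 and 2095, against 642 and 837).

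Combo against 2DG asked what trametinib added to 2-deoxyglucose. Rescaling lowered the changes by a median of 0.26, the most over both lines, and values are those after rescaling. ERK targets fell, with Etv4 at -4.69 ± 0.29, Dusp6 at -2.73 ± 0.09, Spry4 at -2.02 ± 0.10 and Ccnd1 at -1.01 ± 0.08, and Slc2a1 fell too (-1.02 ± 0.05). Kras (0.46 ± 0.06), Txnip (0.85 ± 0.09), Ddit3 (1.21 ± 0.08) and Bcl2l11 (0.59 ± 0.12) rose, all with limma adjusted p of at most 0.00503. Hk2 (-0.34 ± 0.05), Arrdc4 (-0.10 ± 0.10), Hspa5 (0.04 ± 0.02) and Asns (-0.05 ± 0.05) did not pass (adjusted p of 0.066 to 0.702). Of these, Hk2 passed after rescaling (adjusted p = 4.71e-05). Cd74 (2.91 ± 0.15), the sulfotransferase gene Sult1c2 (2.82 ± 0.10) and Tgfb2 (2.77 ± 0.08) were among the largest rises, and Prl2c3 (-4.47 ± 0.08), Prl2c2 (-4.11 ± 0.09) and Mrc1 (-3.35 ± 0.14) among the largest falls besides Etv4 (adjusted p of at most 2.56e-07). The short RNA genes mt-Tc and Mir186 were called up and Snord73a down (adjusted p of 0.019 to 0.0447). In 2DG and in Combo, mt-Tc had 0, 0, 0 and 7.51 TPM against 20.1, 35.7, 8.56 and 8.48, Mir186 0, 0, 23.1 and 0 against 28.7, 27.8, 12.2 and 6.16 and Snord73a 9.87, 254, 9.37 and 13.8 against 0, 0, 7.74 and 0, AK192 first. Each of these 3 calls was lost with some 1 library left out, that of Snord73a without AK192 2DG replicate 2 (adjusted p = 0.157).

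In the ERK output list, 17 of 24 measured members fell, 1 rose and 6 did not pass (18 fell and 2 rose adjusted over the list alone, 21 and 2 rescaled). Dusp5 was at -3.04 ± 0.08, with camera adjusted p = 6.45e-21 (0.409 with estimated correlation). Glycolysis and glucose uptake was called down, where 4 of 21 fell, 2 rose and 15 did not pass (4 fell and 2 rose adjusted over the list alone, 16 and 2 rescaled). Slc16a3 was at -1.78 ± 0.12, with camera adjusted p = 0.00198 (0.951 with estimated correlation). Of replication genes, 18 of 30 fell and 12 did not pass (20 fell adjusted over the list alone, 29 rescaled). Tk1 was at -1.70 ± 0.10, with camera adjusted p = 1.17e-18 (0.473 with estimated correlation). Of mitosis genes, 13 of 25 fell and 12 did not pass (15 fell adjusted over the list alone, 24 rescaled). Kif23 was at -1.18 ± 0.06, with camera adjusted p = 2.65e-15 (0.473 with estimated correlation). In ribosome biogenesis, 5 of 24 fell and 19 did not pass (4 fell adjusted over the list alone, 24 rescaled). Odc1 was at -1.02 ± 0.06, with camera adjusted p = 2.32e-09 (0.695 with estimated correlation). ATF4 and CHOP targets were called up, where 16 of 30 rose, 1 fell and 13 did not pass (16 rose and 1 fell adjusted over the list alone, 15 and 7 rescaled). Atf3 was at 2.28 ± 0.07, with camera adjusted p = 0.032 (0.975 with estimated correlation). Rescaling ended this call (camera adjusted p = 0.0838). Of pro-apoptotic genes, 8 of 11 rose and 3 did not pass (8 rose adjusted over the list alone, 7 rose and 2 fell rescaled). Pmaip1 was at 2.23 ± 0.08, with camera adjusted p = 0.00294 (0.758 with estimated correlation). Of lysosome genes, 25 of 31 rose and 6 did not pass (27 rose adjusted over the list alone, 24 rose and 1 fell rescaled). Map1lc3a was at 1.01 ± 0.07, with camera adjusted p = 1.24e-07 (0.772 with estimated correlation). Of interferon genes, 17 of 18 rose and 1 fell (17 rose and 1 fell adjusted over the list alone, 17 and 1 rescaled). Irf9 was at 1.35 ± 0.07, with camera adjusted p = 1.24e-07 (0.409 with estimated correlation). After rescaling it was called with an estimated correlation too, at adjusted p = 0.0244. The p53 targets were called up, where 10 of 16 rose, 1 fell and 5 did not pass (11 rose and 1 fell adjusted over the list alone, 10 and 2 rescaled). Fas was at 1.31 ± 0.09, with camera adjusted p = 0.0234 (0.951 with estimated correlation). For YAP and TEAD targets, 11 of 21 rose, 1 fell and 9 did not pass (12 rose and 1 fell adjusted over the list alone, 11 and 3 rescaled). Cyr61 was at 1.60 ± 0.04, with camera adjusted p = 0.00748 (0.951 with estimated correlation). The deposited medians in AK192 and AK12282 were 0.11 and -0.31 for glycolysis and 0.09 and -0.98 for mitosis (rescaled, -0.27 and -0.42, and -0.33 and -1.12). Over all genes, 4375 rose and 768 fell in Combo relative to 2DG, and after rescaling 3723 rose and 3341 fell. Across genes it correlated at r = 0.666 with Tra against DoxON, which shares no libraries with it. Both called 2433 genes up and 539 down, against 932 and 84.9 if independent (rescaled, 2829 and 2553, against 1105 and 886).

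Non-additivity asked whether the Combo change departed from the sum of the Tra and 2DG changes on the log2 scale. Rescaling lowered the changes by a median of 0.19, and values are those after rescaling. Ddit3 lay above the sum by 0.75 ± 0.12 and Trib3 by 1.33 ± 0.10, as did Cdsn (1.76 ± 0.18), the interferon-induced gene Xaf1 (1.46 ± 0.15) and the noncoding RNA gene Snhg12 (1.36 ± 0.13). Below the sum lay Sprr2a2 (-2.08 ± 0.36), C3 (-1.93 ± 0.14), Serpine1 (-2.00 ± 0.09), Sprr2a3 (-1.88 ± 0.30) and the tetraspanin gene Cd53 (-1.82 ± 0.14), of which the Sprr2a genes are close paralogs, Sprr2a3 was listed at 0 in both AK12282 DoxON libraries and Cd53 in both AK192 Tra libraries. These genes had the same sign in both lines, with Ddit3 further above the sum in AK12282, and limma adjusted p was at most 0.0112. Try5, a trypsinogen gene, was called above the sum (adjusted p = 0.0102) and was listed at 0 in all DoxON libraries, against 10.3, 8.80, 0.749 and 1.48 TPM in Combo. Of the other fixed genes, Kras (-0.53 ± 0.09), Dusp6 (-0.89 ± 0.12), Spry4 (-0.44 ± 0.14), Etv4 (0.00 ± 0.41), Ccnd1 (0.22 ± 0.12), Slc2a1 (-0.34 ± 0.08), Hk2 (0.32 ± 0.07), Txnip (-0.01 ± 0.12), Arrdc4 (0.06 ± 0.14), Hspa5 (0.04 ± 0.03), Asns (0.57 ± 0.07) and Bcl2l11 (-0.03 ± 0.17) did not pass (adjusted p of 0.0656 to 0.859). Of these, Kras, Dusp6, Spry4, Slc2a1, Hk2 and Asns passed after rescaling (adjusted p of at most 0.0462). Of the ATF4 and CHOP targets, 6 of 30 measured members lay above the sum, 1 below it and 23 did not pass. Adjusted over the list alone, 24 lay above and 1 below, and 22 and 1 rescaled. Cth was at 0.87 ± 0.07, with camera adjusted p = 3.66e-11 (0.956 with estimated correlation). For tRNA synthetases, 0 of 17 passed limma's test over all genes (12 at an unadjusted p under 0.05). Adjusted over the list alone 11 lay above the sum, and over all genes after rescaling 13 did. The rescaled median was 0.31, with camera adjusted p = 8.23e-06 (0.956 with estimated correlation). After rescaling, both lists lay above the sum with an estimated correlation too, at adjusted p = 0.0202 and 0.0354. For ribosome biogenesis, 0 of 24 passed limma's test over all genes (20 at an unadjusted p under 0.05), and 20 rose adjusted over the list alone (21 rose over all genes after rescaling), with a rescaled median of 0.43 and camera adjusted p = 2.91e-09 (0.956 with estimated correlation). The mesenchymal list was called below the sum, where 1 of 11, Serpine1, lay below it and 10 did not pass. Adjusted over the list alone 2 lay below, and rescaled 7 lay below and 1 above. The rescaled median was -0.35, with camera adjusted p = 0.000411 (0.956 with estimated correlation). The epithelial and ductal list was also called below the sum, although its median was 0.04 as deposited and its mean -0.09, with a rescaled median of -0.17, where 1 of 15 fell and 14 did not pass (1 fell adjusted over the list alone, 7 rescaled), namely Cldn4 (-0.95 ± 0.21, deposited -0.09 in AK192 and -1.79 in AK12282), with camera adjusted p = 0.0179 (0.956 with estimated correlation). The deposited medians in AK192 and AK12282 were 0.15 and -0.43 for the mesenchymal and 0.21 and -0.33 for the epithelial list (rescaled, -0.16 and -0.43, and -0.07 and -0.33). Over all genes, 66 lay above the sum and 106 below it, and after rescaling 1217 and 1709. With 1 library left out the total ranged from 70 to 2742.

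Within the lines, with DoxOFF, 162 rose and 50 fell in AK192 and 34 rose and 6 fell in AK12282 (rescaled, 1016 and 1246, and 340 and 353). With Tra, 1287 rose and 748 fell in AK192 and 2207 rose and 704 fell in AK12282 (rescaled, 3140 and 3010, and 3403 and 3005). With 2DG, 665 rose and 1787 fell in AK192 and 469 rose and 124 fell in AK12282 (rescaled, 2786 and 3509, and 2150 and 1801). With Combo, 2929 rose and 1077 fell in AK192 and 2976 rose and 1179 fell in AK12282 (rescaled, 3772 and 3522, and 3677 and 3409). With 1 library left out, the AK192 and AK12282 totals ranged from 39 to 380 and 6 to 70 with DoxOFF, 930 to 3044 and 1293 to 4043 with Tra, 812 to 6459 and 124 to 1145 with 2DG and 2382 to 5120 and 2513 to 5278 with Combo. The lowest AK192 2DG total was without replicate 2. In AK192, rescaling raised the changes by a median of 0.22 with 2DG. Genes called in both lines numbered 25 up and 2 down with DoxOFF (0.404 and 0.0220 if independent), 946 and 333 with Tra (208 and 38.6), 275 and 87 with 2DG (22.9 and 16.2) and 2133 and 710 with Combo (639 and 93.1). After rescaling these were 250 and 256 (25.3 and 32.2), 2281 and 2147 (783 and 663), 1529 and 1360 (439 and 463) and 2778 and 2684 (1016 and 879.9). Across genes, the changes of the lines correlated at r = 0.191, 0.576, 0.361 and 0.699 in that order.

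The test of the difference between the lines (AK12282 minus AK192) asked which genes responded differently. With Tra, the tight junction gene Cldn4 was listed at 0 in both AK192 DoxON libraries and had 20.7 ± 7.59 TPM in AK12282 Tra, from 0.118 ± 0.0185 in DoxON (SD, n = 2), and Ccl9 (-0.81, 2.17), Ptgds (0.77, 3.36), the sphingolipid transporter gene Spns2 (1.52, 3.93), the keratin gene Krt14 (3.199, 0.20) and Fxyd3 (4.27, 0.30) differed, with the deposited changes in AK192 and AK12282 in parentheses and limma adjusted p of at most 0.00102. With DoxOFF, Sox9 (-1.13, 0.36), a ductal transcription factor gene, Krt14 (2.20, 0.13) and Bmp2 (2.25, 0.70) differed (adjusted p of at most 0.0352). With 2DG, Sprr1a (-3.67, -1.04), the connexin gene Gjb1 (-0.09, 1.51), the thrombospondin gene Thbs1 (-1.61, -0.09), Cdsn (3.79, 1.64) and Trib3 (3.83, 1.99) differed (adjusted p of at most 0.0257). With Combo, Spns2 (0.09, 2.98), the glutathione transferase gene Gsta1 (3.50, -0.12) and the collagenase gene Mmp13 (1.06, -1.40) differed (adjusted p of at most 0.000661). Each passed after rescaling too, which lowered the difference by a median of 0.14 with Tra and 0.26 with 2DG. The difference was positive for 3 genes and negative for 7 with DoxOFF, 159 and 100 with Tra, 21 and 18 with 2DG and 71 and 97 with Combo. After rescaling it was positive for 57 and negative for 72, 870 and 861, 977 and 604, and 796 and 1182. With 1 library left out, the totals ranged from 1 to 17, 98 to 474, 8 to 3967 and 59 to 312 in that order. In these tests the lane of sequencing went with the line, 1 lane for each.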

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

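Each value here was marked because the test of the difference between the lines (AK12282 minus AK192) passed, with limma for genes and camera for lists, on the deposited values. Treatments are relative to DoxON. All tests of explanations in this part were chosen only after the result was seen, except the tests of left-out libraries and of the lane for cholesterol synthesis. The rescaling used in 2 of them was an alternative fixed before the data were examined.

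For DoxOFF, 3 named genes differed between the lines: Bmp2 (-1.54), Krt14 (-2.07) and Sox9 (1.49), with adjusted p of at most 0.0352.

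For Tra, 9 named genes differed between the lines: Ccl9 (2.98), Cldn4 (4.13), Fxyd3 (-3.96), Krt14 (-3.00), Prl2c2 (1.65), Prl2c3 (1.40), Ptgds (2.59), Serpine1 (1.09) and Spns2 (2.41), with adjusted p of at most 0.0421. Of these, Cldn4 had a whole group listed at 0, so the value depends on the pseudocount.

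For 2DG, 6 named genes differed between the lines: Cdsn (-2.15), Ddit3 (-1.21), Gjb1 (1.60), Sprr1a (2.62), Thbs1 (1.52) and Trib3 (-1.83), with adjusted p of at most 0.0397.

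For Combo, 4 named genes differed between the lines: Arrdc4 (-1.30), Gsta1 (-3.62), Mmp13 (-2.46) and Spns2 (2.88), with adjusted p of at most 0.0212.

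The DoxOFF response differed between the lines in 6 lists, by median difference as deposited and rescaled: ERK pathway output (0.32, 0.30), ATF4 and CHOP targets (-0.14, -0.16), ribosome biogenesis and MYC targets (0.30, 0.27), cholesterol synthesis (-0.28, -0.31), fatty acid synthesis (-0.19, -0.21) and interferon and antigen presentation (-0.14, -0.17). The camera adjusted p was at most 0.0133, and the adjusted p with an estimated correlation was at least 0.927, or 0.177 after rescaling (under 0.05 in 0). Rescaling ended 0 of these calls and added 2.

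The Tra response differed between the lines in 12 lists, by median difference: glycolysis and glucose uptake (-0.0205, -0.17), ATF4 and CHOP targets (-0.12, -0.24), pro-apoptotic BCL2 family and death receptor (0.30, 0.15), G1/S and DNA replication (-0.37, -0.51), G2/M and mitosis (-0.36, -0.50), cholesterol synthesis (-0.59, -0.74), fatty acid synthesis (-0.28, -0.43), lysosome and autophagy (0.36, 0.21), NRF2 targets (-0.0588, -0.20), YAP and TEAD targets (0.34, 0.19), epithelial and ductal (0.15, 0.04) and mesenchymal (0.45, 0.30). The camera adjusted p was at most 0.0382, and the adjusted p with an estimated correlation was at least 0.924, or 0.0623 after rescaling (under 0.05 in 0). Rescaling ended the calls of pro-apoptotic BCL2 family and death receptor (adjusted p = 0.104) and epithelial and ductal (adjusted p = 0.17) and added 1.

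The 2DG response differed between the lines in 7 lists, by median difference: ERK pathway output (0.54, 0.28), ER chaperones and ERAD (0.69, 0.40), ATF4 and CHOP targets (-0.46, -0.75), G2/M and mitosis (-0.0153, -0.29), ribosome biogenesis and MYC targets (0.56, 0.28), fatty acid synthesis (0.45, 0.17) and lysosome and autophagy (-0.00119, -0.28). The camera adjusted p was at most 0.0278, and the adjusted p with an estimated correlation was at least 0.917, or 0.00316 after rescaling (under 0.05 in 2). Rescaling ended 0 of these calls and added 6.

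The Combo response differed between the lines in 11 lists, by median difference: glycolysis and glucose uptake (-0.31, -0.30), ER chaperones and ERAD (0.39, 0.38), ATF4 and CHOP targets (-0.37, -0.39), G1/S and DNA replication (-0.55, -0.54), G2/M and mitosis (-1.02, -1.03), ribosome biogenesis and MYC targets (0.30, 0.29), cholesterol synthesis (-0.90, -0.91), fatty acid synthesis (-0.52, -0.53), NRF2 targets (-0.31, -0.32), YAP and TEAD targets (0.20, 0.14) and epithelial and ductal (0.21, 0.20). The camera adjusted p was at most 0.0211, and the adjusted p with an estimated correlation was at least 0.448, or 0.0058 after rescaling (under 0.05 in 5). Rescaling ended 0 of these calls and added 4.

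The Combo change of cholesterol synthesis genes was lower in AK12282 than in AK192 by a median of -0.90, where 6 of 23 members passed limma over all genes and 19 adjusted over the list alone. A scaling difference, which moves all genes alike, is an unlikely source, since the median over all genes was 0.00282 as deposited. Rescaling moved this difference by a median of only 0.01, and left the list at -0.91. With each library left out in turn the median stayed between -1.11 and -0.66, which argues against 1 library as the source. A lane effect that grows with the change cannot be told apart from a difference between the lines, since each line had 1 lane, and the lines already differed by 1.21 in DoxON. A difference in how the lines regulate sterol genes therefore stays open as an untested hypothesis, with rescaled group medians of 5.07 in DoxON and 5.85 in Combo for AK192, and 6.12 and 5.90 for AK12282.

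Calls over both lines were mostly up in Combo against 2DG, 85.1% of 5143. The 3 top noncoding features alone may not account for this, since 64.9% of calls were up after their removal. After median-of-ratios rescaling 52.7% were up, but that rescaling centres the genes, so a scaling artefact and a true rise of most transcripts per cell cannot be told apart without spiked-in RNA.

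AK192 2DG replicate 2 had 12980 genes above 0, against at least 19313 in the others. A mislabelled sample is unlikely, as over genes of at least 20 TPM it correlated at 0.893 with the other 2DG library and at most at 0.876 with another group of AK192. The large share of the top features does not need to lower the count, since the library with the next highest share had 20146 genes above 0. Lower depth is consistent with the values, as its 1st percentile of TPM above 0 was 9.77 times the highest of the other 19 libraries. Genes at 0 in it made up 62.8% of those under 1 TPM in the other 2DG library and 1.33% above 20 TPM.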

How the results depend on the processing

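Chosen only after the result was seen were the removal of the 3 top features, the estimated correlation after rescaling, the rescaled correlations, and rescaling without AK192 2DG replicate 2. No named gene that had passed changed sign and no called list changed its camera direction under any alternative. The median did change sign under some alternatives for the called lists ERK pathway output with 2DG, NRF2 targets with 2DG, glycolysis in Combo against 2DG and epithelial and ductal for non-additivity. Robust eBayes left all 20 totals of genes within 1.5 times. Named gene calls lost and gained numbered 0 and 19 with median-of-ratios rescaling, 2 and 20 with rescaling without AK192 2DG replicate 2, 1 and 20 with quantile normalization, 0 and 21 with removal of the 3 top features, 0 and 15 with replicate number as a block, 29 and 2 with a fit of only the compared groups, 17 and 1 with a pseudocount of 0.1, 4 and 2 with a pseudocount of 5, 14 and 0 with no filter, 7 and 0 with a filter of 5 TPM and 8 and 0 with robust eBayes. Leaving out 20 libraries in turn lost 202 gene calls and gained 27 in all. Gained with the block were Asns and Ccnd1 with DoxOFF, Bcl2l11, Hk2, Kras and Slc2a1 with 2DG, Bcl2l11 with Combo, Ccnd1 and Spry4 in Combo against Tra, Asns and Hspa5 in Combo against 2DG, Bcl2l11 in Tra against DoxOFF and Asns, Dusp6 and Hk2 for non-additivity. Of 78 list calls at most 3 were lost under any alternative that kept the preset correlation and all libraries, and 8 in all with libraries left out. A fit of fewer libraries has fewer residual degrees of freedom by construction, and otherwise the cause was not tested. Depth was unknown, so its limit was not assessed. A treatment name alone stands for its comparison with DoxON.

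Median-of-ratios rescaling gave DoxOFF 2479, Tra 7667, 2DG 6552, Combo against Tra 6141, Tra against DoxOFF 6527 and non-additivity 2926 over both lines. In AK192 it gave DoxOFF 2262, Tra 6150, 2DG 6295 and Combo 7294, and in AK12282 DoxOFF 693, Tra 6408, 2DG 3951 and Combo 7086. Line differences were then DoxOFF 129, Tra 1731, 2DG 1581 and Combo 1978. Quantile normalization gave DoxOFF 2281, Tra 7625, 2DG 6506, Combo against Tra 6215, Tra against DoxOFF 6582 and non-additivity 3034 over both lines. Within AK192 it gave DoxOFF 2027, Tra 6154, 2DG 6162 and Combo 7311, and in AK12282 DoxOFF 667, Tra 6338, 2DG 4010 and Combo 7137. Differences between lines were DoxOFF 143, Tra 1802, 2DG 1501 and Combo 2107. Replicate number as a block gave DoxOFF 889, 2DG 5192, Combo against Tra 4652, Tra against DoxOFF 5020 and non-additivity 1941 over both lines. In AK192 it gave DoxOFF 602, Tra 4284, 2DG 5626 and Combo 6089, and in AK12282 DoxOFF 123, Tra 5157 and 2DG 1967. For line differences totals were Tra 649, 2DG 1015 and Combo 553. Residual correlations between groups with the same replicate number were -0.05 to 0.14 in AK192 and -0.09 to 0.03 in AK12282. Replicate 2 had the higher share of the 3 top features in 10 of 10 groups and the lower size factor in 9, so the numbers may mark a batch, which is balanced over the groups. Removal of the 3 top features gave DoxOFF 2512, Tra 7782, 2DG 6843, Combo against Tra 6568, Tra against DoxOFF 6558 and non-additivity 2833 over both lines. Within AK192 it gave DoxOFF 2300, Tra 6176, 2DG 6413 and Combo 7202, and in AK12282 DoxOFF 650, Tra 6553, 2DG 4142 and Combo 7108. Line differences were then DoxOFF 143, Tra 1687, 2DG 1375 and Combo 2023. Rescaling without AK192 2DG replicate 2 gave DoxOFF 3967, Tra 8800, 2DG 7019, Combo 9548, Combo against Tra 7490, Tra against DoxOFF 7871 and non-additivity 3844 over both lines. In AK192 it gave DoxOFF 3791, Tra 7533, 2DG 5833 and Combo 8558, and in AK12282 DoxOFF 1414, Tra 7732, 2DG 5457 and Combo 8354. Differences between lines were DoxOFF 658, Tra 3135, 2DG 1606 and Combo 3367. A fit of only the compared groups gave DoxOFF 140, 2DG 228, Combo against 2DG 2878, Tra against DoxOFF 5308 and non-additivity 93 over both lines. Within AK192 it gave DoxOFF 11, Tra 326, 2DG 0 and Combo 713, and in AK12282 DoxOFF 84, Tra 4720, 2DG 2161 and Combo 8104. For line differences totals were Tra 152, 2DG 23 and Combo 91. A pseudocount of 0.1 gave non-additivity 59 over both lines. In AK12282 it gave DoxOFF 17. Line differences were then DoxOFF 0, Tra 86, 2DG 14 and Combo 47. A pseudocount of 5 gave non-additivity 315 over both lines. Differences between lines were DoxOFF 16, Tra 439, 2DG 61 and Combo 331. No filter gave non-additivity 313 over both lines. In AK192 it gave 2DG 1269, and in AK12282 DoxOFF 77. For line differences totals were DoxOFF 49, Tra 440, 2DG 82 and Combo 332. A filter of 5 TPM gave non-additivity 101 over both lines. Line differences were then DoxOFF 0, Tra 136, 2DG 14 and Combo 61.

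An estimated correlation called 0 lists in each of these 8 comparisons. An estimated correlation after rescaling called 4 lists for DoxOFF, 1 for Tra, 2 for 2DG, 3 for Combo, 3 for Combo against Tra, 1 for Combo against 2DG, 0 for Tra against DoxOFF and 2 for non-additivity. For non-additivity, the number of lists called was 8 with a pseudocount of 5, 11 with median-of-ratios rescaling, 9 with quantile normalization and 11 with removal of the 3 top features.

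DoxOFF and Tra changes correlated at 0.597 with shared controls, and at 0.377 (DoxON replicate 1 for DoxOFF) and 0.352 (replicate 2) with split controls. Crosswise lines gave 0.316 and 0.201. After rescaling these were 0.389, 0.372, 0.322 and 0.205.

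With each library left out in turn, the lone library left in a group was assumed to vary like the other groups. The library left out is in parentheses. Over both lines, totals ranged for DoxOFF 148 (AK12282 DoxOFF 2) to 600 (AK192 2DG 2), Tra 3156 (AK12282 Tra 2) to 5541 (AK192 2DG 1), 2DG 1293 (AK12282 DoxON 1) to 5441 (AK192 2DG 1) and Combo 5105 (AK192 Combo 1) to 7191 (AK192 2DG 1). They also ranged for Combo against Tra 1850 (AK12282 Combo 2) to 3715 (AK192 2DG 1), Combo against 2DG 3433 (AK192 Combo 1) to 7680 (AK192 2DG 1), Tra against DoxOFF 1582 (AK12282 Tra 2) to 3877 (AK192 2DG 1) and non-additivity 70 (AK12282 DoxON 1) to 2742 (AK192 2DG 1). Within AK192, totals ranged for DoxOFF 39 to 380, Tra 930 to 3044, 2DG 812 to 6459 and Combo 2382 to 5120. Within AK12282, totals ranged for DoxOFF 6 to 70, Tra 1293 to 4043, 2DG 124 to 1145 and Combo 2513 to 5278. For the difference between lines, totals ranged for DoxOFF 1 to 17, Tra 98 to 474, 2DG 8 to 3967 and Combo 59 to 312. The number of lists called ranged from 9 to 10 for DoxOFF, 12 to 12 for Tra, 9 to 12 for 2DG, 11 to 13 for Combo, 9 to 12 for Combo against Tra, 10 to 11 for Combo against 2DG, 10 to 11 for Tra against DoxOFF and 4 to 9 for non-additivity.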

Other observations

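Several lists were not called on the deposited values in any comparison over both lines. The adjusted p of camera stands in parentheses, from the rescaled values where the median is rescaled. Oxidative phosphorylation genes had medians of 0.04 (adjusted p = 0.843) with DoxOFF, 0.12 (adjusted p = 0.702) with Tra, -0.12 (adjusted p = 0.441) with 2DG and -0.02 after rescaling with Combo (adjusted p = 0.608). Fatty acid synthesis had 0.16 (adjusted p = 0.149), 0.23 (adjusted p = 0.931), -0.18 (adjusted p = 0.533) and, rescaled, -0.00290 (adjusted p = 0.886) in the same order. The pro-survival BCL2 genes, of which 4 were measured, had -0.08 (adjusted p = 0.289), -0.01 (adjusted p = 0.931), 0.21 (adjusted p = 0.114) and, rescaled, 0.14 (adjusted p = 0.813).

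Called only after rescaling were ER chaperones and ERAD (down) and fatty acid synthesis (up) with DoxOFF, N-glycosylation and cholesterol synthesis (up) with 2DG, glycolysis and glucose uptake (down) with Combo, epithelial and ductal (down) in Combo against Tra and glycolysis and glucose uptake and cytosolic tRNA synthetases (down) in Tra against DoxOFF. For non-additivity they were ER chaperones and ERAD, pro-survival BCL2 family, G2/M and mitosis, lysosome and autophagy, NRF2 targets and YAP and TEAD targets (down). The camera adjusted p after rescaling was at most 0.0491, and 0 of them passed with an estimated correlation.

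After the totals were seen, the 7 pairwise comparisons over both lines were each refitted on their 8 libraries with line as a term. All 34 splits into groups of 4 were used. The real and the highest other split called 91 and 3 genes for DoxOFF, 3322 and 5 for Tra, 274 and 6 for 2DG and 5357 and 2 for Combo against DoxON, 3444 and 1 for Combo against Tra, 2635 and 3 for Combo against 2DG and 4532 and 4 for Tra against DoxOFF. In each, only the real split of 34 called as many. Some of the 34 divided a line unevenly, unlike the design, so this does not exclude chance. For non-additivity, 4 of 100 drawn assignments called as many as the real one, which called 93. The highest other assignment called 738, and such draws exchange whole treatments, a structure of the samples.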
